A study of Metallosphaera sedula with 5 samples.

How the data were processed

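The series measured total RNA of the thermoacidophilic archaeon Metallosphaera sedula on 2-colour oligonucleotide arrays. Per the labels' protocols, cells were grown aerobically at 70 °C and pH 2 in a mineral medium with 0.1% yeast extract. They received no supplement (Y), ferrous sulfate at 10 g/L (YFS), potassium sulfate at 6 g/L (YKS), potassium tetrathionate at 10 g/L (YKT) or elemental sulfur at 20 g/L (YS). Cells were subcultured at least 3 times in the same medium and harvested about 24 h after inoculation. Each medium was grown in 2 bottles of 300 mL, but that with ferrous sulfate in 4. RNA was reverse transcribed and labelled with Cy3 or Cy5, per the labels. Each condition was 1 RNA preparation, split between both dyes and hybridised to 2 of 5 arrays that formed a loop: Y with YFS, YFS with YKS, YKS with YKT, YKT with YS and YS with Y. No condition was grown and extracted again in these files, so no value below has a biological replicate.

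The deposited scanner files hold the intensity of each spot and of its local background in both channels, not normalized and not background-subtracted, per the file headers. The scanner software and the image settings are not given in the sources used here. The deposited files also give the percent of saturated pixels per spot; between 15 and 32 probe spots of an array had any, and these were kept. Each array had 15552 spots, of which 3912 were empty and 11640 carried a probe. There were 2326 probes, 2258 with a number between 1 and 2296 and 68 with another code, each spotted at least 5 times. The labels name channel 1 as Cy3 and channel 2 as Cy5, and the files number the channels without dye names; every direction below rests on taking file channel 1 as Cy3. Each spot has a code of 1, 2 or 3 whose meaning is not given in the sources used here. Code 2 marked the empty spots and no others. Code 3 covered 77.9% to 88.4% of the probe spots of an array, and only these spots were used.

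The deposited value table gives log2 ratios per probe made by the authors, with 1 column per array. Set against the scanner values, 4 columns ran as Cy5 over Cy3 and the column of the array with Y and YS ran the other way. With that column turned, the 5 values of each of its 2328 probes summed to 0 within 1e-06, so the authors' values had already been fitted around the loop. Their correlation over probes with the fitted log2 ratios used here lay between 0.893 and 0.957 in size with the turned column at -0.911, and the slopes were 0.819, 0.771, 0.828, 0.860 and -0.808. The column medians were -0.13, 0.13, 0.03, 0.10 and 0.04, and how the table was centred stays unknown. It entered as an alternative, without a test.

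Background was corrected with limma's normexp method and an offset of 50, and log2 Cy5 over Cy3 was normalized within each array by loess on intensity with a span of 0.3, with limma 3.58.1 in R 4.3.3. Empty spots entered the background fit and had no weight in the loess. Usable spots of a probe were averaged per array. A linear model of the loop was fitted to 1 mean log2 ratio per probe and array with limma (lmFit, and eBayes with a trend on intensity) for the 1898 probes with a usable spot on all arrays. The other 428 were not tested; with all spots kept, between 1 and 17 of them per comparison differed 2-fold or more. The model has 4 coefficients and leaves 1 residual degree of freedom per probe, the closure of the loop. The prior degrees of freedom were infinite, so probes of equal intensity had equal standard errors (SE). The loop sum of a probe, which is 0 without error, had an SD of 1.85 (log2) over probes. It holds 5 times a probe's dye bias besides array error, while that bias cancels from the fitted fold changes. Averaged over the spots of a print block, it ran from -3.57 to 2.32 over 48 blocks, which held 67.3% of its variance over spots. The loess on intensity fixed before the data were seen does not remove this, so the SE of the fit carries it. Blocks held 3.56% to 8.77% of the variance of the fold changes. The median SE was 0.86 for a directly hybridised pair of conditions and 1.05 for a pair joined through the loop.

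A probe was called where it differed 2-fold or more and its Benjamini-Hochberg adjusted p from limma was under 0.05, per comparison. Such a p sets the difference of 2 RNA preparations against array and dye error as held in the loop sum, and says nothing of other cultures. That error includes dye bias that cancels from the fold changes, so a probe that was not called is not thereby shown to be unchanged. There were 4 main comparisons, each supplement against Y, and 4 others. On data simulated for YFS minus Y with 200 of 1898 probes changed, the same fit called 1.52% of the 2-fold, 29.0% of the 4-fold and 93.8% of the 8-fold changes, and 1 of 1698 unchanged probes. In that simulation a list of 10 probes raised 4-fold or more reached percentile 100 among random lists and a list of 10 lowered as much percentile 0, while 1 of 20 unchanged lists lay outside the central 95%. Lists changed that far test the percentile little. Errors were drawn per probe without a place on the slide, as dye bias (SD 0.244) and array error (SD 0.621). Location bias can thus stand in part as array error, which does not cancel. The simulation put 8.89% of unchanged probes 2-fold or more apart. In the main comparisons 50 (YS-Y) to 231 (YFS-Y) of all 1898 probes were, so its rates need not hold here.

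Before the data were examined, the comparisons, the alternatives, the gene lists and the rule for named probes were fixed. The rule took the 8 most increased and the 8 most decreased probes of a main comparison among called probes, or among those 2-fold or more apart where fewer than 8 were called, each with at least 3 usable spots per array. It added called members of the lists, and the 3 most increased and decreased called probes of each other comparison. The files do not pair probe numbers with gene names, so the results print at most 2 probes that were higher and 2 that were lower by number for a comparison. List members are also numbered there, and the rest stand in counts. The closing observations also number probes that turned with a setting or formed a run. Of the lists, 12 were fixed by locus number and 19 by product name, and the latter were not used because they need product names. Reading probe number N as locus number N is an assumption. It rests on 9 coded probes that join such a number to the species' locus prefix and on the order of the numbers (see the closing observations). The profiles of those 9 over the arrays correlated with the numbered probe's at a median of 0.434. Of the 9, 2 were over 0.9, while those for number 1513 stood at -0.961 and -0.969. Only 1 of the 9 reached 2-fold on an array, and its correlation was 0.969. For each of those over 0.9, 49 of 2258 numbered probes correlated more strongly, so they test the assumption only weakly. For genes with 2 probes the brighter one was to be used; no named probe had a second one. The lists were drawn from what is known of this organism, in part from publications on arrays of this kind, so their direction is not independent evidence. A list's median was set against 10000 random lists of the same size matched on signal, as a description of these preparations. Random and simulated lists are not runs of neighbouring numbers, which move together (mean correlation 0.274), so these percentiles do not allow for that. Chosen after seeing the data, each list with at least 3 measured members was also set against all windows of as many consecutive tested numbers outside it. No window lay as high as the hdr-like list in YKT-Y or YS-Y (of 1835) or as soxNL-cbsAB in YFS-Y (of 1850), and none as low as soxM in YKT-YKS (of 1847). For soxABCDD'-soxL 12 of 1841 lay as high in YKT-Y and 13 in YS-Y. For fox 40 of 1811 lay as low in YS-Y and 281 in YKT-Y.

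Empty spots gave between 2.97 and 5.65 times the median local background. A probe counted as above background in a channel where the mean of its spots lay over the 95th percentile of the empty spots; that held for 52.5% to 90.0% of probes per channel. Where a condition was at or under that level in both of its channels, a fold is given as a bound, from channel values after loess and Aquantile scaling, which is open to dye bias. File names place the YKT with YKS and the YS with YKT array in one month and the other 3 arrays in another; values within a month come from single arrays or chains of them, keep their dye bias and have no test. A shift shared by both channels of an array cancels in its ratio, and a month term on the ratios was not fitted, because it would take the 1 residual degree of freedom and leave no test. Alternatives were no or plain background subtraction, median centring, print-tip loess, scaling between arrays, the median of spots, all spots, no dim probes, single spots with the array as a block, no trend, the authors' table, and leaving out each array. Chosen after seeing the data were the empty spots as the background level, a fit of numbered probes only, limma's separate-channel fit without a dye term, and the fit with the YKT/YKS and Y/YS arrays turned, which shows what rests on their labels and replaces none of them.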

Results

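Transcript levels of Metallosphaera sedula, an archaeon that grows in hot acid and oxidises iron and reduced sulfur compounds, were compared between 5 growth media on 5 arrays of 2 colours each. All media held yeast extract; 4 of them also held ferrous sulfate (YFS), potassium sulfate (YKS), potassium tetrathionate (YKT) or elemental sulfur (YS), and yeast extract alone (Y) was the reference. The series asks how ferrous iron and reduced inorganic sulfur compounds change transcription, and potassium sulfate gives a salt without either. Each medium was represented by 1 RNA preparation, measured once with each dye on 2 different arrays, with 5 spots per probe and array. Median probe signal ranged from 329 to 428 intensity units per channel, against 172 to 339 for empty spots. The values are log2 fold changes with the SE of the loop fit, over 1898 probes. With 1 preparation per medium, limma's p-values compare preparations, not cultures. Gene lists are named as if probe numbers were locus numbers, an assumption, and were drawn in part from earlier work on this organism, so their direction is not independent evidence. Signs, sizes, SEs and calls rest on the labels' dyes. The SD of the loop sums was 1.85, and 0.981 with the channels of the YKT/YKS and the Y/YS arrays turned. Turned in that way, the fit put 202 calls in YKS-Y in place of 0 and 305 in YFS-Y in place of 11, and the hdr-like median stood at -1.65 (YKT) and -1.83 (YS). With arrays turned, a dye bias that keeps its sign in the file channels enters the loop sum less and no longer cancels from the fold changes. The lower SD and the added calls can hold such bias and do not by themselves show exchanged channels. Much of the loop sum followed the place on the slide: print-tip loess lowered its SD to 0.851 and the median SE of YFS-Y from 0.860 to 0.258.

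With ferrous sulfate, the probes numbered as the soxNL-cbsAB region, which holds cytochrome b and Rieske protein genes of a respiratory complex, lay above yeast extract alone. Of the 5 listed numbers 4 were measured (500, 501, 503 and 504), all 4 were 2-fold or more higher, and none was called. Their median log2 fold change was 1.75, or 3.36-fold, at percentile 100 of random lists, and 1.68 on the 1 array that held both preparations but 3.17 without it. Adjusted over the list alone, 2 of the 4 passed. Of the 4, only probe 501 (1.11) was above background in every channel of all media. Probe 500 stood at 2.57 (SE 0.93, limma adjusted p = 0.374), and at 4.18 without that array. The fox cluster, whose products serve iron oxidation, showed no common direction: the median of its 17 measured probes (469 to 485) was -0.03, with 2 at least 2-fold higher and 2 lower. Its probe 485 fell by 4.003 on the log2 scale (SE 0.74, limma adjusted p = 4.97e-05), and its neighbour 484 stood at 1.61 (SE 0.70, limma adjusted p = 0.778). The lowest value of the comparison belonged to probe 579, which fell by 5.87 (SE 0.73, limma adjusted p = 2.28e-12).

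In all, 85 probes were 2-fold or more higher and 146 lower in YFS than in Y. The test called 11 of them, all lower, with sizes from 2.57 upwards. None of the higher probes was called; 82 probes of either direction had an unadjusted p under 0.05. The probes of the hdr-like region and the soxABCDD'-soxL region had medians of -0.33 and -0.52 here, and 3 members of each were at least 2-fold lower without being called; adjusted over the list alone, 1 member of the latter passed. On the single array that joined YFS and Y, 148 probes were 2-fold or more higher and 207 lower. Print-tip loess called 33 higher and 62 lower probes and kept 9 of the 11 calls, the fit of single spots called 38 and 46, and scaling between arrays kept only 5 of the 11 and added none. By the authors' values 35 probes were 2-fold or more higher and 168 lower.

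Potassium sulfate against yeast extract alone was measured only through the loop, and no probe was called. There were 88 probes 2-fold or more higher and 68 lower, and 13 had an unadjusted p under 0.05 in limma; print-tip loess also called 0, and the fit of single spots 3. The highest log2 fold change was that of probe 1352 at 3.09 (SE 0.84, limma adjusted p = 0.431). The lowest was that of probe 1806 at -3.40 (SE 0.97, limma adjusted p = 0.431), a value that depended on the path: it was -0.11 without either of the arrays that held YFS. The hdr-like and the soxABCDD'-soxL lists lay near 0, with medians of -0.06 and 0.11. In the fox cluster 5 of 17 measured probes were 2-fold or more lower and 1 was higher, with a median of -0.16. Within the month that held Y, YFS and YKS, 287 probes were 2-fold or more higher and 259 lower. The balance turned in the authors' table of values, with 35 higher and 90 lower, and in the separate-channel fit, with 94 and 135.

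With tetrathionate, probe 804 rose by 5.66 on the log2 scale over yeast extract alone (SE 0.98, limma adjusted p = 1.83e-05), which is 50.5-fold. Leaving out 1 array moved this value between 4.02 and 6.75, and with the YKT/YKS and Y/YS arrays turned it was -3.20. Its number is that of the tetH entry in the list for oxidation of other sulfur compounds; tetH codes for a tetrathionate hydrolase, and the list's other entry (sqr) was not among the tested probes. The hdr-like region, whose heterodisulfide reductase-like proteins take part in sulfur oxidation, had all 9 probes (1542 to 1550) above 0. Of these, 8 were 2-fold or more higher and none was called, over all probes. The median was 2.43, or 5.39-fold, and the members ranged from 0.92 to 3.13, at percentile 100 of random lists. When p-values were adjusted over the list alone, 6 of the 9 passed. The soxABCDD'-soxL region, which codes for a terminal quinol oxidase, had a median of 1.16 over 7 probes (285 to 291), with 5 at least 2-fold higher, none called, and a percentile of 99.96. Adjusted over the list alone, 2 of these 7 passed.

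Over all probes, 74 were 2-fold or more higher and 43 lower in YKT than in Y, through the loop. The test called 5, all higher. Turning the YKT/YKS and Y/YS arrays gave 144 higher and 189 lower, with 67 called higher and 103 lower. In the fit as labelled none of the lower ones was called: the lowest, probe 1807, stood at -2.49 (SE 0.84, limma adjusted p = 0.466). Scaling between arrays gave 67 higher and 23 lower probes and plain background subtraction 53 and 18, while the authors' table gave 40 and 74 and the separate-channel fit 128 and 142. Print-tip loess called 13 higher and 2 lower, but kept only 3 of the 5 calls; single spots called 17 and 0. The arrays with YKT and those with Y lay in different months, so no value within a month exists.

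With elemental sulfur, 47 probes were 2-fold or more higher and 3 lower than with yeast extract alone; without the Y/YS array, where dye bias does not cancel, 597 were higher and 534 lower. The test called 3, all higher. With the YKT/YKS and Y/YS arrays turned, 55 were higher and 72 lower, with 32 called higher and 36 lower. Probe 1905 rose by 4.22 on the log2 scale (SE 0.74, limma adjusted p = 2.33e-05) and probe 804 rose by 3.71 (SE 0.80, limma adjusted p = 0.00372). The remaining call was a member of the hdr-like region; its limma adjusted p of 0.0187 was 0.069 without the trend and 0.933 in the separate-channel fit. That region had a median of 1.85, or 3.61-fold, with 8 of 9 probes at least 2-fold higher, 1 called and 1 near 0. Its percentile was 100, and 7 of 9 passed when adjusted over the list alone. The soxABCDD'-soxL region had a median of 0.79, with 3 of 7 at least 2-fold higher, none called, and a percentile of 99.92; adjusted over the list alone 1 passed. With the separate-channel fit that median was 0.09. On the single array that joined YS and Y, 64 probes were 2-fold or more higher and 31 lower, and the hdr-like median was 1.79. Scaling between arrays gave 74 higher and 15 lower probes, the authors' values 24 and 5, and the separate-channel fit 90 and 62. Without the Y/YS array, probe 804 stood at 1.53.

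**Figure D1:**
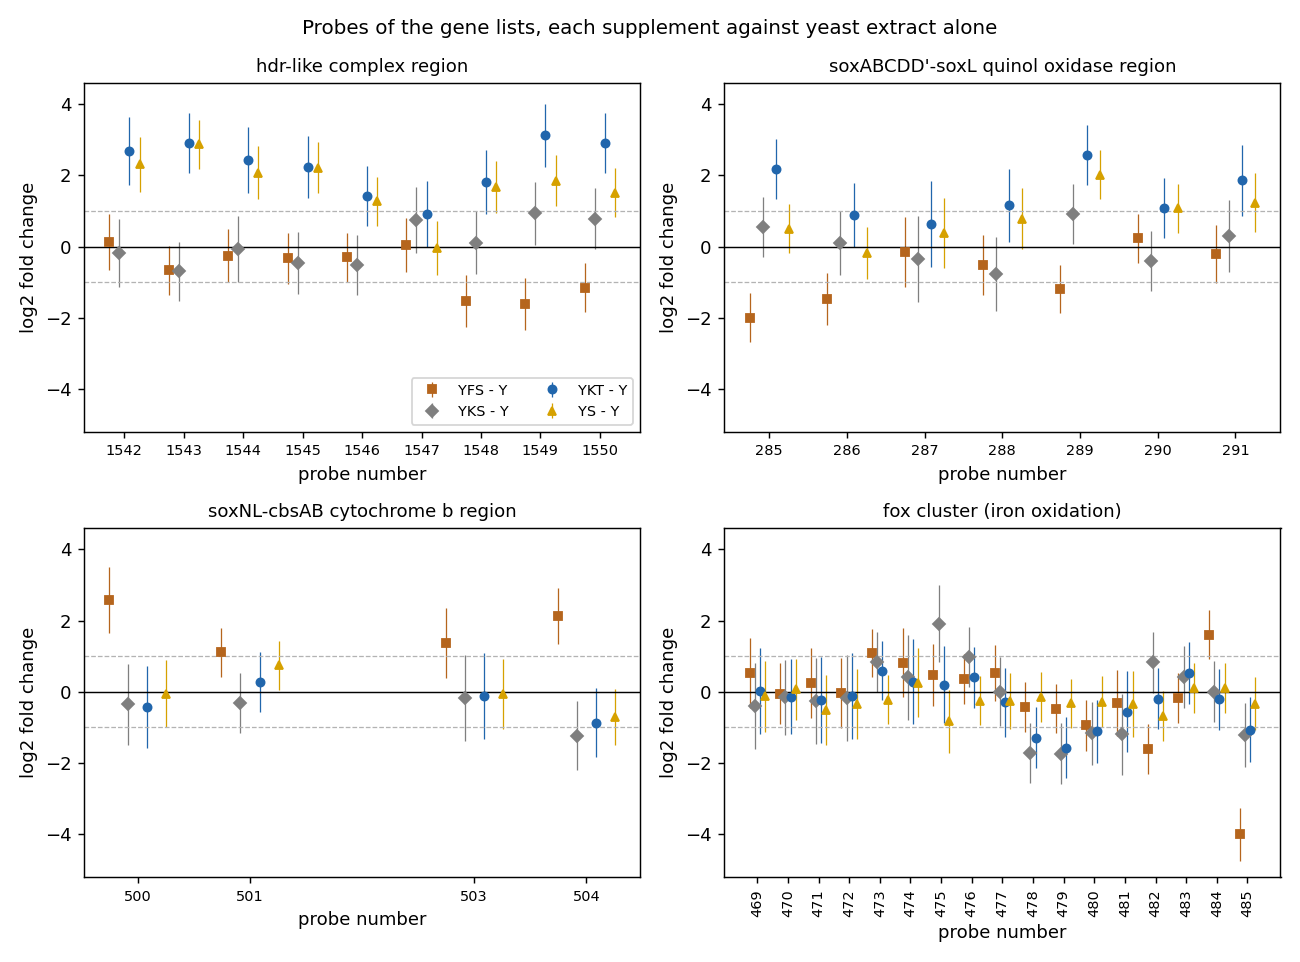
Log2 fold change of each measured probe of 4 gene lists, with each supplement against yeast extract alone; bars are 1 SE of the loop fit, dashed lines mark 2-fold, and list names apply if probe numbers are locus numbers. With tetrathionate (circles) the hdr-like probes lie between 0.92 and 3.13, and with ferrous sulfate (squares) probe 485 of the fox cluster lies at -4.003.

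Both sulfur compounds were also compared on arrays that shared no preparation: tetrathionate with potassium sulfate on one, elemental sulfur with yeast extract alone on the other. Of 25 probes that differed 2-fold or more on both single arrays, 21 were higher with the sulfur compound on both, 1 was lower on both and 3 went opposite ways. With the channels of both arrays turned, the same 21 would be lower on both and 1 higher. Of the 21, 7 belonged to the hdr-like or soxABCDD'-soxL lists. Over all probes the correlation of these log2 ratios was 0.06; it was 0.24 over the probes above and -0.29 over those below the median signal. Probes are not independent replicates. The sulfur compound was in Cy3 on one array and in Cy5 on the other, so a dye bias kept between arrays would push these values apart.

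**Figure D2:**
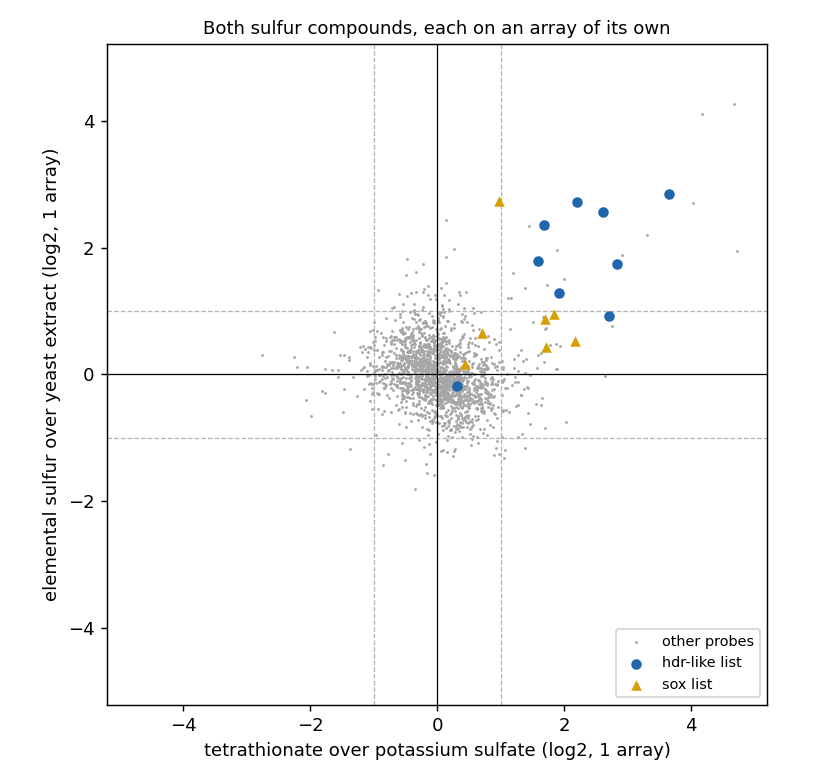
Log2 ratio of each of 1898 probes on 2 single arrays, tetrathionate over potassium sulfate (horizontal) and elemental sulfur over yeast extract alone (vertical); dashed lines mark 2-fold. The 21 probes higher on both lie in the upper right corner, which holds most hdr-like probes (blue circles).

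Against potassium sulfate, tetrathionate gave 46 probes 2-fold or more higher and 26 lower, and limma called 8, all higher. On turning the YKT/YKS and Y/YS arrays, 54 were higher and 113 lower, with 30 called higher and 71 lower. As labelled, probe 804 rose by 5.23 (SE 0.80, limma adjusted p = 1.69e-07) and probe 1905 rose by 4.06 (SE 0.74, limma adjusted p = 4.15e-05); as 1905 was not above background with potassium sulfate, this is given as at least 13.0-fold. The hdr-like median was 2.20, with 2 of 9 members called higher and 8 of 9 adjusted over the list alone. The soxABCDD'-soxL median was 1.56 with none called, over all probes or adjusted over the list alone. The soxM region, which codes for another terminal oxidase, had a median of -0.94 over 5 measured probes, at percentile 0.01, with 2 at least 2-fold lower and none called. With dim probes left out limma called 2, as 4 of the 8 were not tested and 2 lost their call. Print-tip loess gave 48 higher and 13 lower probes and called 25 and 6; no background correction gave 40 higher and 12 lower, and the separate-channel fit 52 and 66. On the single array, 91 probes were 2-fold or more higher and 55 lower.

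Ferrous sulfate against potassium sulfate, which sets 2 sulfate salts side by side, gave 59 probes 2-fold or more higher and 154 lower. The test called 3 higher and 25 lower. Probe 504 of the soxNL-cbsAB region rose by 3.36 (SE 0.79, limma adjusted p = 0.00507), and the median of that region's 4 measured probes was 2.24 at percentile 100, with 2 passing when adjusted over the list alone. Probe 579 fell by 5.86 (SE 0.73, limma adjusted p = 2.35e-12). Of the fox cluster 2 probes were called, both lower, while its median was 0.24. The hdr-like and the soxABCDD'-soxL lists had 1 member each called lower, and 2 of each passed when adjusted over the list alone. Without the YKS/YFS array probe 504 stood at 1.35. Scaling between arrays left 9 calls in this comparison and print-tip loess made 130; the separate-channel fit gave 93 higher and 129 lower probes. On the single array, 86 probes were 2-fold or more higher and 195 lower.

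Elemental sulfur against tetrathionate gave 105 probes 2-fold or more higher and 71 lower, with 2 called higher and 1 called lower. Probes 1806 and 1807 rose by 3.51 and 3.04 (SE 0.79 and 0.69, limma adjusted p = 0.0102 for each), and probe 373 fell by 2.73 (SE 0.69, limma adjusted p = 0.045). Scaling between arrays ended these calls. Print-tip loess kept only that of probe 1807: it put 373 at -0.27 and 1806 at 3.53 (limma adjusted p = 0.0607). By the authors' values 105 probes were higher and 34 lower. Without the array that held both preparations probe 1806 stood at 7.89 and on that array alone at 2.41. The hdr-like median was -0.35 and none of its members was called. Elemental sulfur against potassium sulfate gave 188 higher and 145 lower probes, with 4 called, all higher; with the YKT/YKS and Y/YS arrays turned it gave 62 and 83, with 9 called higher and 36 lower. Print-tip loess called 34 higher and 18 lower there. Within the month of 2 arrays 340 were 2-fold or more higher and 290 lower, and within the month of 3 arrays 418 and 426.

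For the 3-hydroxypropionate/4-hydroxybutyrate cycle, the carbon fixation pathway of this organism, 15 of 16 numbers were measured and the medians against yeast extract alone were 0.16 (YFS), -0.06 (YKS), 0.08 (YKT) and 0.04 (YS), with no member called. For the hydrogenase region 19 of 38 were measured and the medians were 0.20, -0.01, 0.07 and 0.08, with no member called. With ferrous sulfate 7 of the 19 were not above background, so that median is uncertain; it was 0.46 over members above background in every channel. Adjusted over the list alone, 1 passed with ferrous sulfate. The copper resistance list copRTA had 2 of 3 measured and medians of -0.50, -0.42, -0.14 and 0.08; with potassium sulfate 1 of the 2 was not above background. The doxBCE oxidase had 3 of 3 measured and medians of 0.54, 0.49, 0.23 and 0.27. The soxM region had medians of 0.05, 0.51, -0.43 and -0.23. The doxDA list had 1 of 3 measured, at -1.47, -1.41, -0.83 and 0.11, and none of these probes was called. The 2 numbers of the list of rusticyanin-like proteins had no tested probe. The fox cluster had a median of -0.19 with tetrathionate and -0.26 with elemental sulfur, at percentiles 3.58 and 0.33 of random lists, with no member called. Against windows of consecutive numbers these medians stood out less: 281 and 40 of 1811 windows lay as low. The soxNL-cbsAB medians were -0.33 with potassium sulfate, -0.27 with tetrathionate and -0.05 with elemental sulfur. The list with tetH held only probe 804, at 0.43 with potassium sulfate. With ferrous sulfate this probe was not above background, and no value of the main fit is given.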

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

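Chosen after the data were seen were the settings with empty spots as background, with numbered probes only, with separate channels and with the YKT/YKS and Y/YS arrays turned; the separate-channel fit with a dye term could not be estimated and was not run. No paired analysis was possible because each medium had 1 RNA preparation. A mean over several probes of a gene changed nothing, as 0 named probes had a second probe. Of the 2-fold counts 64 moved by more than 1.5 times and 104 did not; of the counts of calls 34 did and 78 did not. Of list medians 810 moved by less than their spread, 88 by more and 7 turned from a value beyond that spread. Others also changed sign, from values within their spread. Of values of named probes 1233 kept their direction and their side of the threshold or, without a test, moved by less than their SE. Of the others, 75 passed the threshold newly, 24 no longer did, 137 without a test moved by more than their SE and 35 turned. Except where stated, the cause was not tested. Signal over background limited the dim probes: empty spots reached 2.97 to 5.65 times the local background.

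Without background correction, 2-fold counts were 126 (YFS-Y), 66 (YKS-Y), 61 (YKT-Y), 120 (YFS-YKS), 111 (YS-YKT) and 189 (YS-YKS), and the tetH list was 2.81 with YS. Plain subtraction gave 152, 84 and 71 for YFS, YKS and YKT against Y, and 132 for YFS-YKS. Print-tip loess called 95 (YFS-Y), 15 (YKT-Y), 10 (YS-Y), 130 (YFS-YKS), 31 (YKT-YKS), 24 (YS-YKT) and 52 (YS-YKS). Scaling between arrays called 5 (YFS-Y), 10 (YKT-Y), 8 (YS-Y, 89 at 2-fold), 9 (YFS-YKS), 0 (YS-YKT) and 7 (YS-YKS), with hdr-like medians of 2.87 (YKT) and 2.46 (YS) and tetH at 4.84 (YS). Single spots called 84, 3, 17 and 10 for YFS, YKS, YKT and YS against Y, 75 (YFS-YKS), 22 (YKT-YKS), 37 (YS-YKT) and 41 (YS-YKS). Separate channels called 1 (YKS-Y), 15 (YKT-Y), 6 (YS-YKT) and 28 (YS-YKS), with 270 (YKT-Y), 152 (YS-Y) and 118 (YKT-YKS) at 2-fold. In that fit the medians were -0.70 (fox, YS), -0.16, 1.58 and 0.0886 (soxABCDD'-soxL, YFS, YKT and YS), 0.57 and 1.43 (hdr-like, YKS and YS) and 0.39 and 0.52 (hydrogenase, YKT and YS), and probe 2167 turned to 0.22 from -1.92 (YKS-Y). The authors' table gave 29 at 2-fold (YS-Y), 1.18 (soxNL-cbsAB, YFS) and -0.64 and 2.06 (hdr-like, YFS and YKT). Without dim probes 139 (YFS-YKS) were at 2-fold and 2 were called (YKT-YKS, where 4 of 8 calls were not tested and 2 were lost). Of soxNL-cbsAB only probe 501 was then left, at 1.11 and 0.74 (YFS and YS), and the hydrogenase medians were 0.46 and -0.20 (YFS and YS). With all spots, more list members entered: fox 0.25 (YFS), doxDA -0.0486, -0.0431 and 0.55 (YFS, YKS and YKT), tetH and sqr 2.83 (YKT) and 1.75 (YS). The month of 3 arrays gave 355 (YFS-Y), 546 (YKS-Y), 95 (YS-Y) and 844 (YS-YKS), with hydrogenase at 0.30, tetH at -0.66 and probe 2167 turned to 0.0518 (YKS-Y). The month of 2 arrays gave 146 (YKT-YKS), 289 (YS-YKT) and 630 (YS-YKS).

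Leaving out each array ends the cancelling of dye bias and leaves no test. The 2-fold counts then ranged from 355 to 1087 (YFS-Y), 546 to 781 (YKS-Y), 452 to 885 (YKT-Y), 95 to 1131 (YS-Y), 281 to 1097 (YFS-YKS), 146 to 1084 (YKT-YKS), 289 to 1071 (YS-YKT) and 630 to 844 (YS-YKS). Probes that turned were 2167 (-4.87 to 0.0518) and 478 (-2.89 to 0.0317) in YKS-Y, 1806 (-5.46 to 0.0234) and 2145 (-3.85 to 2.39) in YKT-Y and 1048 (-1.80 to 1.24) in YS-Y. Medians of hdr-like ranged from -0.12 to 0.33 (YKS), 1.61 to 2.05 (YKT) and 1.24 to 1.79 (YS), and of soxABCDD'-soxL from 1.30 to 1.68 (YKT). Those of soxNL-cbsAB ranged from 1.68 to 3.17 (YFS), -0.87 to 0.36 (YKS), -1.19 to 0.21 (YKT) and -1.27 to 0.13 (YS). Those of fox ranged from 0.00139 to 0.63 (YFS), -0.98 to -0.12 (YKT) and -0.64 to -0.20 (YS). The tetH list, probe 804 alone, ranged from -0.67 to 2.06 (YFS), -0.66 to 2.07 (YKS), 4.02 to 6.75 (YKT) and 1.53 to 4.26 (YS). As probe 804 was not above background with ferrous sulfate, its YFS range is no measure of size or direction. Further list medians also moved. Those of doxBCE ranged from 0.91 to 1.99, 0.26 to 1.30, -0.30 to 1.41 and -1.30 to 0.66, and of doxDA from -1.81 to -0.10, -2.10 to -0.39, -1.86 to -0.15 and -1.26 to 0.45 (YFS, YKS, YKT and YS). The carbon fixation cycle ranged from -0.50 to 0.21 (YFS), -0.52 to 0.13 (YKS) and -0.0831 to 0.99 (YS), and hydrogenase from -0.00907 to 0.30 (YKS) and 0.0372 to 0.52 (YKT).

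Dye bias does not cancel in the fit with the YKT/YKS and Y/YS arrays turned. There limma called 305 (YFS-Y), 202 (YKS-Y), 170 (YKT-Y), 68 (YS-Y), 218 (YFS-YKS), 101 (YKT-YKS), 151 (YS-YKT) and 45 (YS-YKS), and 2-fold counts were 382 (YKS-Y), 333 (YKT-Y), 127 (YS-Y), 167 (YKT-YKS) and 145 (YS-YKS). Medians with YKT turned to -1.65 (hdr-like), -0.76 (soxABCDD'-soxL) and -3.20 (tetH), and with YS to -1.83, -0.93, -4.97 and 0.13 (fox). The soxABCDD'-soxL median with YFS moved to -0.14. Others changed sign from medians within their spread, to -0.19, 0.64 and 0.42 (soxM, YKS, YKT and YS), -0.57 (doxBCE, YS), -0.71 (doxDA, YS) and -0.32 (hydrogenase, YKT). Probes that turned were 1920 in YKS-Y (-0.0547), 804, 371, 372, 812, 814, 815 and 1905 in YKT-Y (-3.20, -0.39, -0.78, -1.53, -3.21, -2.58 and -5.02), and 804, 372, 814, 815, 1542, 1543, 1545, 1905, 1273 and 1048 in YS-Y (-4.97, -1.98, -3.22, -2.69, -2.84, -3.13, -3.00, -4.01, 0.58 and 1.83). In YKT-YKS 804, 815 and 1905 turned to -3.97, -3.99 and -4.27, and in YS-YKS 1905 turned to -3.26.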

Other observations

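Written before their results were seen were the tests on neighbouring slide positions, on exchanged channels after print-tip loess and on loop sums of neighbouring numbers; the other tests were chosen after. Probes of neighbouring numbers often differed together. Over the 4 main comparisons there were 23 runs of at least 3 neighbouring numbers that were 2-fold or more apart in one direction. In YKT-Y, probes 371 to 373 formed a run with a median log2 fold change of 3.77, all 3 called in limma (after print-tip loess 373 stood at 0.74 and was not called), and 814 to 816 one with a median of 3.25 and none called. Both runs were also 2-fold or more higher in YS-Y, with medians of 1.75 and 2.32 and none called. In YKS-Y, 1645 to 1649 had a median of 1.80 and the fox-list probes 478 to 481 one of -1.46, with none called. In YFS-Y, 1632 to 1637 had a median of -1.57, with none called.

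Against Y the medians of the hdr-like and soxABCDD'-soxL lists lay higher with both sulfur compounds, though with YS 1 member of each lay below 0 and only 1 of all was called. In YKT-YKS 2 hdr-like members were called, and in YS-YKS 1. Of the 16 members of both lists 15 had opposite signs of Cy5 over Cy3 on the YKT/YKS and Y/YS arrays, each toward the sulfur compound, against 19.7% of all probes. A dye bias alike on both arrays would not give this. Such a bias already cancels from the fitted fold changes, and the pattern was found on these same arrays, so the signs add no separate evidence. The lowest list median within a month, on single arrays, was 0.647. A shift shared by both channels cancels in these ratios in any case, so this value does not test such a shift between months. The higher median in YKS-Y was 0.106, which argues against potassium or sulfate as the whole cause. The hdr-like one was 0.57 in the separate-channel fit and reached 0.33 with an array left out. An increase of these transcripts with reduced sulfur compounds is a candidate explanation that stays a hypothesis, as it was found and tested on the same preparations. Exchanged channels on these same 2 arrays would turn the direction.

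That neighbouring numbers move together could come from places on the slide. Probes side by side with numbers more than 20 apart had a mean correlation of 0.0419 (1441 pairs), against 0.274 for neighbouring numbers (1574 pairs), which argues against it. The 23 runs stood against at most 5 in 1000 shuffles of the numbers, which is consistent with numbers that follow gene order. The probes are not independent replicates.

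The loop sums were far from 0, with an SD of 1.85 for probes below and 1.84 for probes above the median signal. Dye bias of single probes as the whole cause left the value for neighbouring numbers open (-0.00513), but loop sums of probes side by side with numbers far apart correlated at 0.759, which argues against it. A dye bias that follows the place on the slide would lower the SD under print-tip loess, and so would array error by place. A fall already followed from the 67.3% of the variance of the loop sums over spots that lay between blocks. It therefore adds no separate evidence for either. After print-tip loess the SD was 0.851. There, turning 1 array raised the SD to 1.03 or more, which argues against 1 exchanged array, and turning any other pair than the YKT/YKS and Y/YS arrays raised it to 1.08 or more. An exchange of channels on that pair cannot be told apart from correct labels. Before print-tip loess, with the location bias still in, the SD spoke for it (0.981 turned). A dye bias with the same sign on all arrays would also lower the SD on turning. The correlation of neighbouring numbers, with that location bias also in, spoke against an exchange (0.0952 turned, interval 0.044 to 0.15, and -0.056 to 0.0434 as labelled). After print-tip loess neither decided. The SD was 0.842 turned, a difference of -0.00896 (interval -0.061 to 0.0429). The correlation was 0.121 turned and 0.07 as labelled, a difference of 0.0511 (interval -0.00933 to 0.124). As labelled its interval was 0.0161 to 0.119, so it too lay above 0 there, though shared responses cancel round a loop labelled as hybridised. The authors' values closed round the loop only once their Y/YS column, deposited the other way, was turned to Cy5 over Cy3. As deposited the sums reached 7.302 in size. With that column turned, their fit goes with both arrays as labelled, which leaves an exchange before their fit open. As Y/YS is 1 of the 2 arrays in doubt, the closure is no separate support for its label.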
